A study of Mus musculus with 4 samples.

How the data were processed

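Tfcp2l1 binding was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in wild-type mouse embryonic stem cells. Per the labels' protocols, the cells grew in medium with 1000 units/mL of LIF, 3 µM CHIR99021 (an inhibitor of GSK3) and 1 µM PD0325901 (an inhibitor of MEK), a combination known as 2i with LIF. Per the series' design text, the immunoprecipitation used 10 µg of a custom antibody against mouse Tfcp2l1. There were 4 libraries, in 2 repeats of 1 ChIP library and 1 input library (sheared chromatin without immunoprecipitation). Nothing in the labels says whether the repeats came from separate cultures, so the spread between them may be technical.

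The analysis started from 2 peak lists, 1 per repeat, which the authors called separately and did not pool. Per the file headers, peaks were called with MACS 1.4.1 for the ChIP library against the input library of the same repeat. The p-value threshold was 1e-05, the tag size 35 bp, the fragment length d 200 bp and the effective genome size 1870000000 bp. The band width was 300 and the model fold limits were 10 and 30. Per the file headers, at most 2 duplicate tags were kept per position, the smaller library was scaled to the larger, and the local background came from windows of 1000 and 10000 bp. The submitters' processing notes also name CASAVA 1.8.2. The aligner is not given in the sources used here. The deposited tag count of a peak is the whole number of ChIP tags in it, without normalization. The deposited score is 10 times the -log10 of the MACS p-value. The deposited fold enrichment is the ratio of ChIP tags at the summit to the local background that MACS estimated. The deposited FDR, in percent, is the empirical rate MACS obtained by exchanging ChIP and input, per the file headers. All fold enrichments and scores printed are the authors' values for single peaks. They were used to describe, rank or filter peaks within a list, and to compare matched peaks between the lists.

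Depth came from the file headers. In repeat 1 the authors counted 21026205 ChIP tags (19353473 after duplicate filtering) and 20347402 input tags (18446758 after filtering). In repeat 2 they counted 25425095 ChIP tags (22555373) and 27370213 input tags (23825930). Scores tie: 964 peaks of repeat 1 and 664 of repeat 2 carry exactly 3100, so fold enrichment was used for ranking. Intervals of percentages are exact (Clopper-Pearson) 95% binomial intervals. Those of ratios and odds ratios are 95% intervals symmetric on a log scale. Both kinds cover counting error only.

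The processing notes name the mm9 build, but the positions are those of GRCm38. Peaks on chromosome Y reach 90.8 Mb, and summits gather at gene ends of GRCm38 on all 19 autosomes in both lists. Genes were therefore taken from a RefSeq gene table of GRCm38.p6, with 21887 protein-coding genes. That table gives the start and end of each gene without strand or exons. The planned distance to a transcription start site was replaced by the distance to the nearer end of a gene, and "inside a gene" means between its start and end, with exons and introns not told apart. A planned search for the Tfcp2l1 motif needed a genome sequence and was not run.

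A peak was called shared if it overlapped a peak of the other repeat by at least 1 bp. The share was set against 1000 random placements of the other list within the same chromosomes, one-sided, with 0.001 as the smallest possible p. Fold enrichments of shared peaks that matched one-to-one were correlated across regions, which are not replicates, so no p is given. Summits of shared peaks in repeat 1 were measured to gene ends against 1000 random placements. Genes with a shared peak within 10 kb of either end were counted in 23 gene lists written before the data were examined, by two-sided Fisher's exact tests against all other protein-coding genes with Benjamini-Hochberg adjustment over the 23 lists at 0.05. Log2 odds ratios have 0.5 added to each cell of the table. These tests are across genes or regions and not across replicates. Of the list genes, 307 matched the gene table and 1 (Dux) did not, and 11 stood in more than 1 list. The genes named were fixed by rule before the data were examined: the nearest genes of the 10 shared peaks with the best mean rank of fold enrichment, up to 4 members per list with a shared peak within 10 kb in order of mean rank, up to 2 members per list without a peak of either repeat within 10 kb, and Tfcp2l1. Some genes that the rule names are not reported here. Genes named outside that rule are said to be.

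Alternatives fixed beforehand were stricter FDR, fold and score limits, other definitions of a shared peak, rank by score or tags, other distances to genes, each repeat alone, and 10000 random lists matched on the distance to the nearest neighbouring gene. Alternatives added after seeing the data were random rotation of each chromosome's peaks and a window covering the gene and 10 kb around it. Others added then were autosomes alone and a background without name groups that had few shared peaks. These groups were defined by symbol prefix, such as Olfr, Vmn and Gm, and not by common descent or expression. They are called low-count name groups below. The steps were tested on simulated data. A list made to keep 60.2% of repeat 1 gave back 100% of the kept peaks as shared. Kept peaks were moved by less than the shortest peak length, so this checks only the code. Of random lists of 15 genes, 4.5% had an unadjusted p below 0.05 (Fisher's test). Of lists of 15 genes made to have a peak of repeat 1 at 12, 0% did so, so an excess of that size could not be called. Brute-force overlap of the 1676 peaks of repeat 1 on chromosome 19 differed for 0 peaks. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.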

Results

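Tfcp2l1, a transcription factor of the CP2 family that acts downstream of LIF in naive mouse embryonic stem cells, was mapped in wild-type cells kept in 2i with LIF. The question set by the design was where in the genome the factor is bound, judged by enrichment of ChIP over input in 2 repeats. Repeat 1 held 57614 peaks from 19353473 filtered ChIP tags, and repeat 2 held 51610 peaks from 22555373. Median peak length was 929 bp and 945 bp, median tags per peak 46 and 48, and median fold enrichment over input 12.1 and 10.2. The highest FDR in either list was 0.12%. Peaks held 22.5% of the filtered ChIP tags in repeat 1 and 17.3% in repeat 2, over 57.7 Mb and 52.0 Mb. Pairs of values below are repeat 1 and then repeat 2, and positions are in GRCm38.

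The strongest region shared by both repeats lay on chromosome 7 at 80185527 to 80187791, 0.629 kb from Sema4b, with 186-fold and 141-fold enrichment. Next came a region inside Plekhh1 on chromosome 12 (79035075 to 79036351, 178-fold and 128-fold) and a region 32 bp from an end of Rbpj, the DNA-binding effector of Notch signalling (chromosome 5, 53554110 to 53557620, 177-fold and 128-fold). A region inside Esrrb, which encodes a nuclear receptor of the naive pluripotency network, was among the 10 strongest (chromosome 12, 86503204 to 86505341, 168-fold and 127-fold). Another of these lay far from any protein-coding gene, on chromosome 5 at 119309870 to 119311192, with the pluripotency factor gene Tbx3 the nearest at 360 kb (175-fold and 118-fold). The other regions of the 10 were inside Dync1h1, Smchd1 and Xxylt1, 8.94 kb from Chka and 6.86 kb from Ubald2, with 164-fold to 178-fold enrichment in repeat 1 and 121-fold to 127-fold in repeat 2. Ranking by tags kept 1 of the 10, so the membership of this set rests on the ranking by fold enrichment. Ranking by score cannot test it, because all 10 had the tied score of 3100 in both lists and other peaks lay above it.

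Binding sites at pluripotency genes recurred in both repeats. A peak 4.73 kb from Nanog, a core regulator of naive pluripotency, had 135-fold and 95.4-fold enrichment, and a peak inside the DNA demethylase gene Tet2 had 176-fold and 80.5-fold. A peak near Pou5f1, which encodes Oct4, had 69.1-fold and 54.6-fold. In all, 43851 of 57614 peaks of repeat 1 (76.1%, 95% interval 75.8% to 76.5%) overlapped a peak of repeat 2, and 43785 of 51610 peaks of repeat 2 (84.8%, 84.5% to 85.2%) overlapped a peak of repeat 1. Random placement gave means of 4.29% and 4.77%, with 4.57% and 5.09% the highest of 1000 placements (p = 0.001 for each, one-sided permutation, the smallest possible). Summits of these 43851 peaks of repeat 1 lay a median of 28 bp from those of their matches, 88.3% of them within 100 bp. No interval had the same start and end in both lists. Random placement ignores gaps and regions to which tags cannot be mapped, so the chance share is a lower guide.

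Sites of high enrichment were found again nearly without exception. In the strongest of 10 equal bins of each list, with at least 43.4-fold enrichment in repeat 1 and 32.2-fold in repeat 2, all 5761 and all 5161 peaks were shared. These bins included the regions at Sema4b, Rbpj, Esrrb, Nanog and Tet2. In the weakest bin, 36.4% of peaks in repeat 1 (35.2% to 37.7%) and 56.2% in repeat 2 (54.8% to 57.6%) were shared. Shared peaks had a median of 58 and 56 tags, against 28 and 28 for the 13763 peaks found in repeat 1 alone and the 7825 found in repeat 2 alone.

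**Figure D1:**
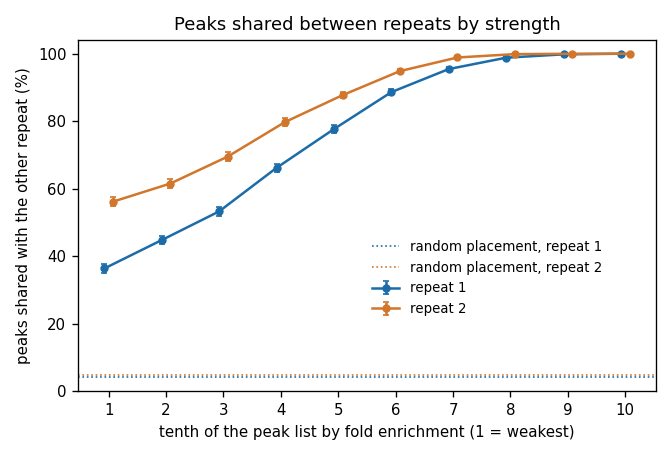
Percent of peaks shared with the other repeat (vertical axis) in each of 10 equal bins of a list ranked by fold enrichment (horizontal axis, 1 is the weakest), with points for repeat 1 and repeat 2, bars for exact 95% binomial intervals and dotted lines for random placement. The share runs from 36.4% to 100% in repeat 1 and from 56.2% to 100% in repeat 2, above 4.29% and 4.77% by random placement.

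Sites with high enrichment in repeat 1 tended to have high enrichment in repeat 2. Bcl3, a target of Stat3, had its strongest nearby peak at 158-fold and 115-fold. The gene of the tight-junction protein claudin 4, Cldn4, had 157-fold and 117-fold, and Etv4, a transcription factor gene induced by ERK signalling, had 158-fold and 103-fold. Peaks of middle or lower rank included that near the erythroid gene Hba-a1 (10.7-fold and 13.7-fold, against list medians of 12.1-fold and 10.2-fold). Another lay near the smooth muscle actin gene Acta2 (7.25-fold and 9.03-fold). Genes were named by mean rank over both lists, so only the correlation over all pairs bears on agreement. Across the 42559 one-to-one pairs, Spearman's rho of fold enrichment was 0.813 and Pearson's r of its log2 was 0.86. These correlations are across regions, which are not independent replicates.

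**Figure D2:**
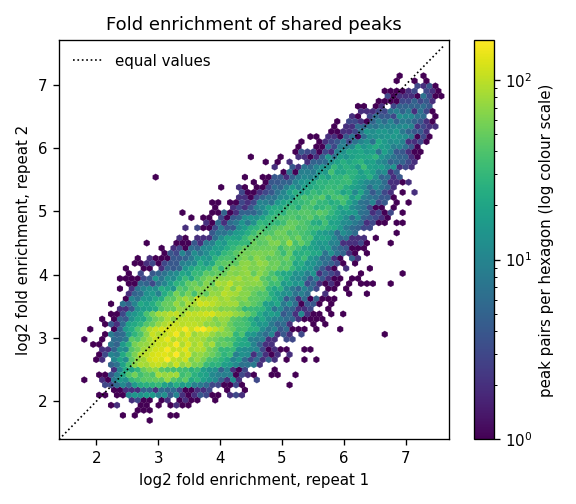
Log2 fold enrichment of one-to-one shared peaks in repeat 1 (horizontal axis) and repeat 2 (vertical axis), with colour for the number of peak pairs per hexagon on a log scale and a dotted line for equal values. The 42559 pairs form 1 band (Spearman's rho 0.813), with medians over all 43851 shared peaks of repeat 1 at 15.5-fold and their matches in repeat 2 at 11.8-fold.

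Shared sites lay close to genes more often than random placement gave. A summit fell 23 bp from an end of Dusp6, an ERK phosphatase gene (107-fold and 66.3-fold), 0.119 kb from an end of Stat3, the transcription factor activated by LIF (112-fold and 51.4-fold), and 0.158 kb from an end of the epithelial protease gene St14 (101-fold and 42.8-fold). Of the 43851 shared summits, 14.04% were within 1 kb of an end of a protein-coding gene, against 3.22% by random placement, a 4.36-fold excess. Within 10 kb lay 44.9% against 22.1%, a 2.03-fold excess, and 55.7% were inside a gene against 41.3%, a 1.35-fold excess (p = 0.001 for each, one-sided permutation, the smallest possible). Summits beyond 10 kb of any protein-coding gene end numbered 24155 (55.1%), and 4330 (9.87%) were beyond 100 kb. The start and the end of a gene could not be told apart, and open chromatin was not analysed here.

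Naive pluripotency genes had shared sites nearby more often than other genes. Of the 22 members of this list, 21 had a shared peak within 10 kb of an end (95.5%, 77.2% to 99.9%), against 59.8% of other protein-coding genes (adjusted exact p = 0.00631, Fisher's test). Besides Nanog and Tet2, the strongest sites were at Fbxo15, an Oct4 target gene (101-fold and 67.5-fold), and within Tbx3 (93.7-fold and 40.0-fold, 7 shared peaks within 10 kb). The member without a shared peak was Nr0b1 on chromosome X, named after its values were seen, which had a peak in 1 repeat. All 15 genes of the LIF and Stat3 pathway had a shared peak (100%, 78.2% to 100%, adjusted exact p = 0.00853, Fisher's test). Among them were the feedback inhibitor Socs3 (98.7-fold and 59.7-fold), Stat3, Bcl3 and the adhesion molecule gene Icam1 (87.7-fold and 49.0-fold). These lists share 3 genes, Tfcp2l1 among them. With a window of 1 kb the naive list stayed past the threshold (13 of 22, adjusted exact p = 0.0403) and the LIF list did not (8 of 15, adjusted exact p = 0.152). With 50 kb, where 80.1% of other genes had a shared peak, the lists had 21 of 22 and 15 of 15 members with one (adjusted exact p = 0.238 and 0.209, Fisher's test). All 15 members of the LIF list gave an unadjusted exact p of 0.0534 there, so it could not pass above other genes.

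The list named epithelial junctions was the third above other genes. Besides junction genes it holds other epithelial genes, such as St14, Spint1 and Rab25, so it does not test junction genes alone. Of its 16 members, 15 had a shared peak within 10 kb (93.8%, 69.8% to 99.8%, adjusted exact p = 0.0318, Fisher's test). The sites were strong at Cldn4, at the protease inhibitor gene Spint1 (145-fold and 121-fold), at St14 and at Cldn7 (70.8-fold and 49.1-fold). Esrp1, named after its values were seen, was the member without a shared peak. Of all 35 genes with the prefix Cldn, compared after seeing the data, 16 had a shared peak within 10 kb (45.7%). That was below the 59.9% of other genes but not past the threshold (adjusted exact p = 0.146 over 59 name families, Fisher's test). The epithelial list kept 15 of 16 members but lost its call when the window took in the gene body. The log2 odds ratio was then 2.51 against 2.80 (adjusted exact p = 0.0907, Fisher's test), and the share of other genes rose to 64.5%. Again with 15 of 16, the call was lost when the low-count name groups left the background (2.35, adjusted exact p = 0.135, Fisher's test). There the share of other genes rose to 67.0%. The call was also lost with 50 kb (log2 odds ratio 1.36, adjusted exact p = 0.367, Fisher's test). There even a list with 16 of 16 members had an unadjusted exact p of 0.0546 (Fisher's test), so the epithelial list could not pass above other genes.

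**Figure D3:**
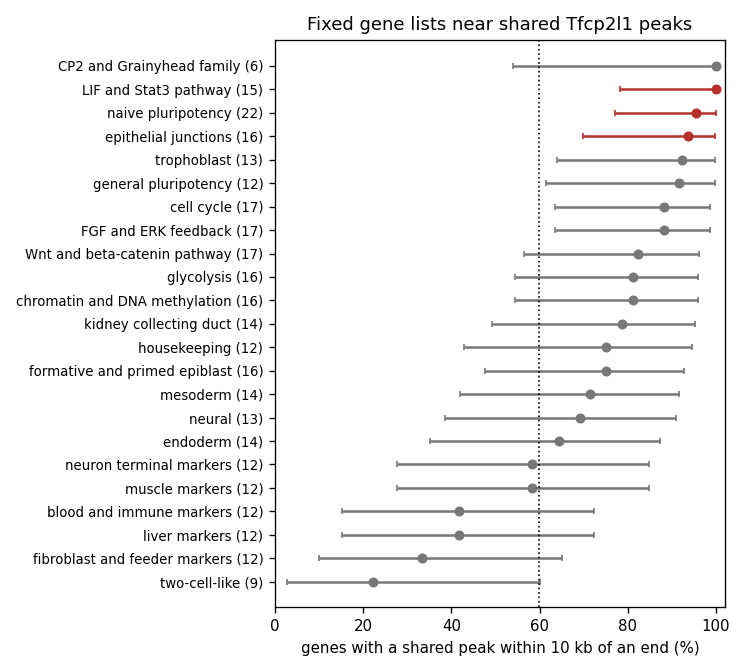
Percent of genes in each list with a shared peak within 10 kb of an end (horizontal axis), with the number of members in brackets, bars for exact 95% binomial intervals and a dotted line at 59.8%, the share of all protein-coding genes. Red marks the 3 lists with an adjusted p below 0.05, namely LIF and Stat3 pathway (100%), naive pluripotency (95.5%) and epithelial junctions (93.8%).

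Other groups tied to self-renewal had high shares that did not pass the threshold in the main setting. General pluripotency had 11 of 12 members with a shared peak (adjusted exact p = 0.102), with the strongest at Foxd3 (127-fold and 69.1-fold), Utf1 (81.2-fold and 66.9-fold) and Rex2 (68.7-fold and 62.6-fold), the last uncertain because it belongs to a group of similar zinc finger genes. This list passed in 5 of 10 alternatives, each repeat alone among them (12 of 12, adjusted exact p = 0.0304 for repeat 2 and 0.0459 for repeat 1), but within 1 kb it had 3 of 12 against 28.9% of other genes (adjusted exact p = 1). FGF and ERK feedback had 15 of 17 (adjusted exact p = 0.0876), including Etv4, Dusp6, Fgf4 (63.1-fold and 39.2-fold, 9 shared peaks) and Spry4 (62.0-fold and 37.7-fold). It passed in 3 of 10 alternatives, with the lowest adjusted exact p = 0.00317 for fold enrichment of at least 10 in both repeats, and had 6 of 17 within 1 kb (adjusted exact p = 0.804). The Wnt and beta-catenin pathway had 14 of 17 (adjusted exact p = 0.183), with sites at Cdx1 (86.8-fold and 75.4-fold), Apc, Tcf7l1 and Myc, and no peak of either repeat within 10 kb of an end of T or Nkd1, although 1 shared peak lay inside Nkd1. It passed in 1 of 10 alternatives, by nearest gene (16 of 17, adjusted exact p = 0.0267). Cell cycle genes had 15 of 17 (adjusted exact p = 0.0876), led by Ccnd3 (136-fold and 95.8-fold), Ccnd2 (82.9-fold and 72.2-fold) and Trp53 (85.8-fold and 55.3-fold). They passed in 4 of 10 alternatives, with the lowest adjusted exact p = 0.0169 for repeat 1 alone (17 of 17).

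Regulators of chromatin and DNA methylation had 13 of 16 members with a shared peak (adjusted exact p = 0.218). Tet1, a DNA demethylase gene, had 7 shared peaks within 10 kb, the strongest at 159-fold and 114-fold, and Kdm1a had 83.2-fold and 91.5-fold, while Tet3 had no peak of either repeat. Glycolysis genes also had 13 of 16 (adjusted exact p = 0.218), with Aldoa at 107-fold and 63.2-fold and Hk2 at 68.7-fold and 81.6-fold. Housekeeping genes had 9 of 12 (adjusted exact p = 0.489), among them Actb (24.9-fold and 25.3-fold). Kidney collecting duct genes, from a tissue in which Tfcp2l1 is also expressed, had 11 of 14 (adjusted exact p = 0.298), with Atp6v1b1, a proton pump subunit gene, at 96.3-fold and 109-fold and Elf3 at 109-fold and 69.8-fold. Of these lists, chromatin regulators (15 of 16) and housekeeping genes (12 of 12) passed with repeat 2 alone (adjusted exact p = 0.0304 for each), and kidney genes by nearest gene (13 of 14, adjusted exact p = 0.0475), each in 1 of 10 alternatives.

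Shares of embryonic lineage genes ran from 64.3% to 92.3%, none past the threshold. Formative and primed epiblast had 12 of 16 members with a shared peak (adjusted exact p = 0.417), with Nodal at 72.3-fold and 71.8-fold and Otx2 at 41.6-fold and 30.2-fold, and no peak of either repeat within 10 kb of an end of Sox3 or Cdh2, although 4 shared peaks lay inside Cdh2. Mesoderm had 10 of 14 (adjusted exact p = 0.518), with Eomes at 64.9-fold and 51.8-fold and no peak at T or Hand2. Neural genes had 9 of 13 (adjusted exact p = 0.668), with Olig2 at 56.2-fold and 49.1-fold. Endoderm had 9 of 14 (adjusted exact p = 0.868), with Sox17 at 57.5-fold and 59.3-fold and none at Hnf4a. Trophoblast had the highest share of these, 12 of 13 (adjusted exact p = 0.0876), with the keratin gene Krt8 at 105-fold and 77.7-fold, and passed in 3 of 10 alternatives, among them fold enrichment of at least 10 in both repeats (adjusted exact p = 0.0185), but had 5 of 13 within 1 kb (adjusted exact p = 0.804).

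Markers of differentiated cells had shares at or below that of other genes, none past the threshold. Neuron terminal markers and muscle markers each had 7 of 12 (adjusted exact p = 1 for each), with Nefl at 102-fold and 63.2-fold and Mylpf at 38.0-fold and 24.7-fold. Liver markers had 5 of 12 (adjusted exact p = 0.349), with Hpx at 58.9-fold and 26.3-fold and none near Alb or Serpina1a. By nearest gene the liver list had 3 of 12 and fell below other genes (adjusted exact p = 0.0475), in 1 of 10 alternatives. Blood and immune markers had 5 of 12 (adjusted exact p = 0.349), with none near Ptprc or Cd8a. Fibroblast and feeder markers had 4 of 12 (adjusted exact p = 0.183), with Col1a1 at 88.2-fold and 77.3-fold and none near Col3a1 or Thy1. The lowest share was that of genes of the two-cell-like state, 2 of 9 (22.2%, 2.81% to 60.01%, adjusted exact p = 0.102). Sites lay near Zscan4c (11.1-fold and 12.6-fold) and Zscan4f (10.6-fold and 13.7-fold), whose near-identical copies make the positions uncertain. Copies that tags of 35 bp cannot tell apart could also hide sites at members without a peak, which was not tested. The two-cell-like list fell below other genes in 2 of 10 alternatives, each repeat alone (adjusted exact p = 0.0335 for repeat 1 and 0.0408 for repeat 2). By nearest gene it had 5 of 9 against 61.5% (adjusted exact p = 0.774), and random lists matched on the distance to the nearest gene had a mean of 4.05 members with a peak (adjusted permutation p = 0.398). Apart from those for matched random lists, p in these paragraphs are from Fisher's exact tests, and 8 of the 23 lists had an unadjusted p below 0.05 in the main setting.

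The CP2 and Grainyhead family, to which the factor itself belongs, had a shared peak at all 6 members (adjusted exact p = 0.183, Fisher's test). Its Grainyhead member Grhl3 had 10 shared peaks within 10 kb, the strongest at 46.1-fold and 40.8-fold, and Ubp1 had a site of 95.2-fold and 43.6-fold. Tfcp2l1 itself carried 8 shared peaks in the gene or within 10 kb of it. The strongest lay inside the gene on chromosome 1, at 118645481 to 118646682 (31.3-fold and 39.8-fold) and at 118647686 to 118648881 (35.3-fold and 23.6-fold). The peaks outside the gene lay at 118689552 to 118690679 (26.1-fold and 15.4-fold) and at 118622653 to 118623372 (7.73-fold and 4.64-fold), and one lay across an end at 118627667 to 118629085 (14.3-fold and 10.99-fold).

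**Figure D4:**
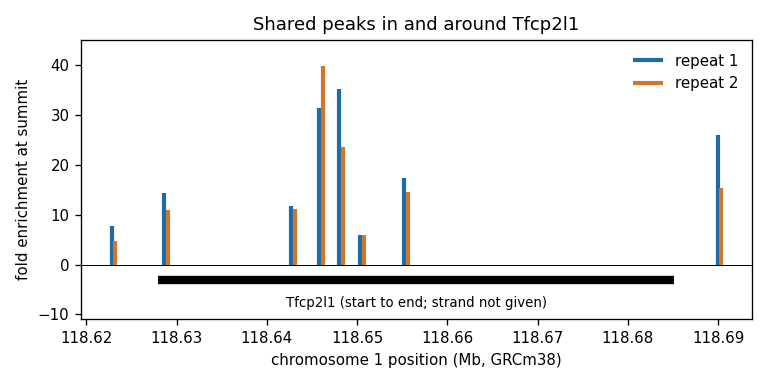
Fold enrichment of shared peaks (vertical axis) at their summits in repeat 1 and repeat 2 along chromosome 1 (horizontal axis, Mb in GRCm38), with the black bar for the extent of Tfcp2l1. Of the 8 shared peaks drawn, the highest values are 35.3-fold in repeat 1 and 39.8-fold in repeat 2, at neighbouring sites inside the gene.

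Chromosome X carried few sites. It had 575 shared peaks for 966 protein-coding genes, or 0.595 per gene, against 2.09 per gene over the autosomes, where the lowest was chromosome 7 with 1.36 and the highest chromosome 12 with 2.80. Per Mb the values were 3.46 on X and 18.0 on the autosomes. The naive pluripotency gene Nr0b1, which lies on X, had a peak in 1 repeat without a shared one. Chromosome Y had 18 shared peaks. Shares of X genes against autosomal genes with a shared peak within 10 kb were 25.6% and 62.2%.

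**Figure D5:**
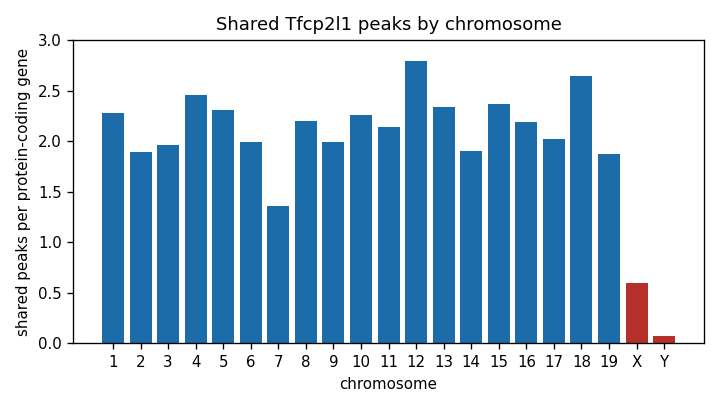
Shared peaks per protein-coding gene (vertical axis) for each chromosome (horizontal axis), with red bars for X and Y. The autosomes lie between 1.36 and 2.80, and X is at 0.595.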

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

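No paired analysis was possible because the input libraries enter only through the authors' peak calls. The only values per library used here were depths and the ChIP tag counts of peaks. The rotation of peaks, the window around the whole gene and the background without low-count name groups were chosen after seeing the data. So were the autosomes alone and the joining distances of clusters. Limits on FDR of 1% and 5% removed no peak, the alternatives of the motif search were not run, and shares near genes and between repeats stayed above random placement under each setting run. Peak numbers dropped to 35291 and 26161 with fold enrichment of at least 10, and to 37687 and 33813 with a score of at least 100. The share of peaks found again then was 68.5% and 91.9% by fold and 77.9% and 86.5% by score, and it was 67.5% and 75.3% for summits within 100 bp. The limits were applied to both lists, and fold enrichment ran higher in repeat 1 (median ratio 1.32). Peaks of repeat 1 could thus lose a partner that fell under the fold limit in repeat 2. Spearman's rho was 0.831 by score, 0.834 by tags and 0.821 with summits within 100 bp. The weakest of 10 bins of repeat 2 by score was shared at 50.8%. The number of lists above other genes, 3 at first, was 3 within 1 kb, 0 with 50 kb and 2 with the gene and 10 kb around it. It was 2 without low-count name groups, 6 by nearest gene and 7 with fold enrichment of at least 10 in both repeats. It was 5 on autosomes alone and 6 with matched random lists. Without replicate 1 and without replicate 2 it ranged from 5 to 7. The number of lists below other genes, 0 at first, was 1 by nearest gene, 1 without replicate 1 and 1 without replicate 2. The cause of these changes was not tested. No call past the threshold changed direction. The log2 odds ratio of 11 lists that passed in neither setting changed sign in 18 values. Within 1 kb these were general pluripotency (-0.14), formative and primed epiblast (-0.65), endoderm (-1.02), Wnt (-0.28) and chromatin (-0.65). With 50 kb they were liver (0.059), muscle (0.93) and blood (0.059). By nearest gene they were neuron terminal markers (0.77) and housekeeping (-0.23). With the gene and 10 kb around it the value for neuron terminal markers did so (0.58). The log2 odds ratio also changed sign without low-count name groups for endoderm (-0.23), and with fold enrichment of at least 10 for kidney (-0.054). Without replicate 1 it did so for endoderm (-0.017) and muscle (0.11), and without replicate 2 for endoderm (-0.26), muscle (0.40) and neuron terminal markers (1.03, against -0.36 without replicate 1). Groups of at least 5 shared peaks, 1097 when joined within 10 kb, numbered 332 within 5 kb and 2069 within 20 kb, and the largest went from 20 peaks to 14 and 41. Naive pluripotency kept its call in 9 of 10 alternatives, the LIF list in 8 and epithelial junctions in 7. Lists of the size of the LIF and epithelial ones could not pass above other genes with 50 kb. Of the 89 genes with a shared peak that the naming rule picks, 84 kept one with fold enrichment of at least 10 and 44 within 1 kb. Lists of 6 to 22 genes limit what can be resolved.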

Other observations

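The test of the genome build was chosen only after the result was seen, as were the gene families, clusters of sites and kinds of gene described here and the genes and regions named in them. Part of the sites gathered in clusters. Joining shared peaks with summits within 10 kb of each other gave 26583 groups, of which 18013 were single peaks (mean of 30344 in 100 random placements) and 1097 held at least 5 peaks (mean of 36.97, highest 53). The largest had 20 peaks each, at Irf2bpl on chromosome 12 (86859255 to 86933340, 74.1 kb) and at Rnf220 on chromosome 4 (117282787 to 117399268, 116 kb), while the highest number in 100 random placements was 11. These placements ignored gene positions, gaps and regions to which tags cannot be mapped. As shared sites lay near genes more often than placed ones, the excess of groups cannot be told apart from that. Which cluster is largest and how many peaks it holds depend on the joining distance. Within 5 kb the largest had 14 peaks, at Tnrc18 on chromosome 5 (highest of 8 in random placements), and within 20 kb it had 41, around Irf2bpl (highest of 14), while a slightly wider distance that was tried first gave 25, around Rnf220. Clusters of 19 lay around Hsp90ab1 on chromosome 17 and at Ahdc1 and Wasf2 on chromosome 4, and clusters of 18 at Zmynd8 on chromosome 2 and around Sparc on chromosome 11. Esrrb carried a cluster of 16 peaks over 62.9 kb on chromosome 12 (86462860 to 86525752), with a highest enrichment of 168-fold in repeat 1 and 127-fold in repeat 2.

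Gene families differed widely in how many members had a shared peak within 10 kb. Of 59 name families with at least 30 protein-coding genes, 22 lay above and 15 below other genes by Fisher's exact test with Benjamini-Hochberg adjustment. Cell division cycle (Cdc) genes had 29 of 32 (90.6%), ring finger (Rnf) genes 71 of 83 (85.5%), zinc finger (Zfp) genes 289 of 397 (72.8%) and solute carriers (Slc) 263 of 375 (70.1%). Olfactory receptors (Olfr) had 79 of 1110 (7.12%), vomeronasal receptors (Vmn) 15 of 355 (4.23%) and the Rhox homeobox genes 1 of 33 (3.03%). Copies that tags of 35 bp cannot tell apart could lower such counts, and neighbouring members can share a peak. Neither was tested for these families. Among other kinds of gene, tRNA genes had 256 of 408 (62.7%, 57.9% to 67.4%) within 10 kb, lncRNA genes 48.3% and pseudogenes 21.9%.

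The strongest peak of repeat 1 without a match lay 471 bp from Prmt3 with 37.9-fold enrichment and 114 tags. The peak with the most tags in repeat 1, 2745 over 8840 bp on chromosome 13 at 119595343 to 119604182, had only 4.48-fold enrichment and no match in repeat 2. Of the unmatched peaks, 97.0% in repeat 1 and 99.3% in repeat 2 had a score under 200.

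The processing notes name mm9, so the positions may have been those of that build. Against this, on 19 of 19 autosomes the share of summits within 1 kb of a GRCm38 gene end was at least 1.74 times the highest share with the genes moved along the chromosome, in both lists.

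The scarcity of sites on X was set against the tag density of a single X copy and against gene families whose copies cannot be told apart. Autosomal shared peaks scoring at least 100 in both repeats were assumed strong enough to pass at the tag density of a single copy. Neither that limit nor the presence of 1 X copy was tested. Against those autosomal peaks, X stayed at a ratio of 0.425 per gene (0.391 to 0.462). It was 0.664 (0.610 to 0.722) with a score of at least 200, which was chosen after the first ratio. Outside name families of 10 or more genes, the odds ratio of X genes to autosomal genes having a shared peak was 0.183 (0.155 to 0.215), and with both explanations together it was 0.302 (0.257 to 0.355). Each upper bound lies below 1, so at these limits neither explanation alone accounted for the whole deficit. The combined ratio cannot decide on both together, because a score of 100 may be too low to pass at a single copy. The combined comparison was run only with a score of at least 100. As the single-copy ratio rose with the limit, the combined one does not settle a stricter limit. The intervals treat peaks and genes as independent, although sites clustered. No biological explanation was tested, and repeats on X outside named families stay open, so a lower density of Tfcp2l1 sites on X may be taken as a hypothesis only.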
